A study of Mus musculus with 8 samples.

How the data were processed

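Gene expression was measured in mouse bone marrow cells on 8 Affymetrix Mouse Genome 430 2.0 arrays, with 4 arrays of cells transduced with a retrovirus carrying Evi1 and GFP and 4 of cells transduced with GFP only (mock). Per the labels' protocols, the bone marrow came from C57BL/6 mice primed with 5-fluorouracil, a drug that removes dividing blood cells, and the transduced cells were kept for 48 h in a methylcellulose culture medium before GFP-positive cells were sorted. Total RNA was isolated with a column kit and biotin-labelled as cDNA, per the labels' protocols. The series design states that independent experiments were performed. The labels do not say which arrays came from the same experiment.

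The submitters' processing notes name GCOS, the scanner software, and RMA, a method that corrects background, normalizes between arrays and summarizes the probes of a probe set; no versions are given in the sources used here. The deposited values are log2 signals per probe set, as RMA gives them. The base of the logarithm was inferred from the values: the highest value, 13.6, is too large for a natural logarithm of a scanner reading. Whether a background correction based on GC content was used is not given in the sources used here. The median log2 signal of the arrays lay between 3.34 and 3.40, so the arrays had been put on a common scale, which hides any difference in the total amount of RNA. RMA compresses differences at low signal, and no detection calls were used, so a probe set at a low level has no known lower limit. The number of arrays limits the precision: the median standard error of a difference was 0.11 on the log2 scale.

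The table held 45101 probe sets. The 64 control probe sets were left out of the tests and used as controls, which left 45037. In the platform annotation of 2016, 34945 of these had 1 gene symbol, 932 had several and 9160 were not listed; a probe set with several symbols was tested but is not given a gene name here. By Entrez identifier, 34741 of the 34945 probe sets matched the RefSeq gene table of assembly GRCm38.p6, and 0 symbols had to be updated. No genome build is named for the array values, and no coordinates are given. A gene was represented by the probe set with the highest mean over the 8 arrays among those with its symbol only, which gave 18193 genes. Of the 549 different genes in the lists fixed beforehand, 43 had no probe set of their own in this annotation, and 2 of the genes planned to be named singly were among those without one; they are not analysed here.

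Differences are Evi1 minus mock on the log2 scale. They were tested with limma 3.58.1 in R 4.3.3 (linear model per probe set, moderated variance, two-sided) and adjusted over all 45037 probe sets by the Benjamini-Hochberg method, with a threshold of 0.05. Intervals are 95% intervals from the same model. Gene lists, 20 in number, were tested against all other genes with camera from limma at a preset correlation between genes of 0.01, adjusted over the 20 lists, and again with the correlation estimated from the arrays. The mean over a list's members was also compared between the groups by an exact two-sided permutation test over the 70 assignments of arrays to groups, in which the smallest possible p is 0.0286. Controls were compared with the same exact test.

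The groups, tests, gene lists, alternatives and naming rule were fixed before the data were examined. The rule named every Mecom probe set, up to 10 genes per direction with the greatest differences among those past the threshold whose 4 arrays did not overlap the 4 of the other group (or, where a direction had none, the 5 genes with the smallest p), up to 4 members of each list with the smallest p, and Gata2, Adgrg1 and Itga6. The lists covered stem and progenitor cells, blood lineages, stromal cells, genes described as targets of EVI1, signalling and chromatin pathways, proliferation, stress and handling responses, HOX genes and sex-linked genes.

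The test was tried on simulated arrays with the spread of each of the 45037 probe sets and 200 probe sets changed by known amounts. For the comparison of Evi1 with mock, 41.8% of changes of 0.5, 91.0% of changes of 1 and 100% of changes of 2 on the log2 scale were recovered, with 10 false calls. In simulated lists over 18193 genes, 5 of 5 lists of 25 genes shifted by 0.25 and 0 of the unshifted lists were called. The simulated genes were independent of each other, whereas the estimated correlation within the real lists reached 0.21. The simulation therefore says nothing about false calls of lists in the real arrays, where splits other than the labelled one called up to 5 lists.

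The alternatives were a replicate block, filters on low signal, other scalings (array medians, quantile normalization, hybridization spike-ins), other variance models, array weights, an ordinary 2-sample test, other rules for representing a gene, other list tests and leaving out each array in turn. Arrays were compared pairwise before averaging, and none was a copy of another: the root mean square difference of a pair was at least 0.223.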

Results

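The series addressed which genes respond to Evi1, a zinc finger transcription factor encoded at the Mecom locus that is active in blood stem cells and in some myeloid leukaemias. GFP-positive primary mouse bone marrow cells were profiled 48 h after transfer to culture, 4 arrays after transduction with Evi1 and GFP and 4 after transduction with GFP only (mock). The labels describe the replicates as independent experiments. The 8 arrays were alike: Pearson correlations across probe sets lay between 0.991 and 0.996. Along the first principal component, which held 32.6% of the variance among the upper part of the probe sets by signal, mock replicate 1 (-0.63) and Evi1 replicate 4 (0.63) lay at opposite ends, and the ranges of the groups overlapped.

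Few probe sets passed the threshold between Evi1-transduced and mock-transduced cells. Probe set 1425923_at of Mycn, a MYC-family transcription factor, fell from 12.65 ± 0.02 (SD, n = 4) in mock cells to 2.98 ± 0.34 (SD, n = 4) in Evi1 cells, a log2 difference of -9.68 ± 0.15 (SE; limma, adjusted p = 7.15e-10). It stood at percentile 99.96 of all probe sets in mock cells and 43.65 in Evi1 cells. The other two Mycn probe sets did not follow it: they differed by -0.10 (95% interval -0.58 to 0.38) and 0.07 (-0.11 to 0.25), at levels of 6.15 and 5.73 in mock cells.

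Immunoglobulin kappa light chain signals were higher in Evi1 cells. Probe set 1452417_x_at, annotated to several kappa genes, rose from 1.81 ± 0.23 to 5.05 ± 0.63 (SD, n = 4 each), a log2 difference of 3.24 ± 0.27 (SE; limma, adjusted p = 0.00618). Probe set 1427455_x_at, with the same annotation, rose from 3.75 ± 0.19 to 6.34 ± 0.66, a difference of 2.59 ± 0.27 (adjusted p = 0.0411). A further one, 1427660_x_at, was higher by 2.74 ± 0.31 and did not pass (adjusted p = 0.0532). Probe sets of this kind can share probes, so they are not independent measurements. The greatest difference under the single symbol Igk was 1.98 ± 0.33 (adjusted p = 0.353), while the other Igk probe sets differed by -0.15 to 0.20. The call on 1427455_x_at was lost when any 1 of 6 arrays was left out, without both arrays at the ends of the first component (adjusted p = 0.621), without the lowest 25% (0.0590) or the lower part (0.0669) of probe sets by signal, and in the ordinary 2-sample test (0.216). Its difference stayed between 2.35 and 2.86 with each array left out in turn, and at 2.55 without both end arrays. The call on 1452417_x_at was lost without mock replicate 1 (adjusted p = 0.0509), Evi1 replicate 2 (0.0740) or both end arrays (0.288), at differences of 3.17, 3.23 and 3.09, and in the ordinary 2-sample test (0.180).

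**Figure D1:**
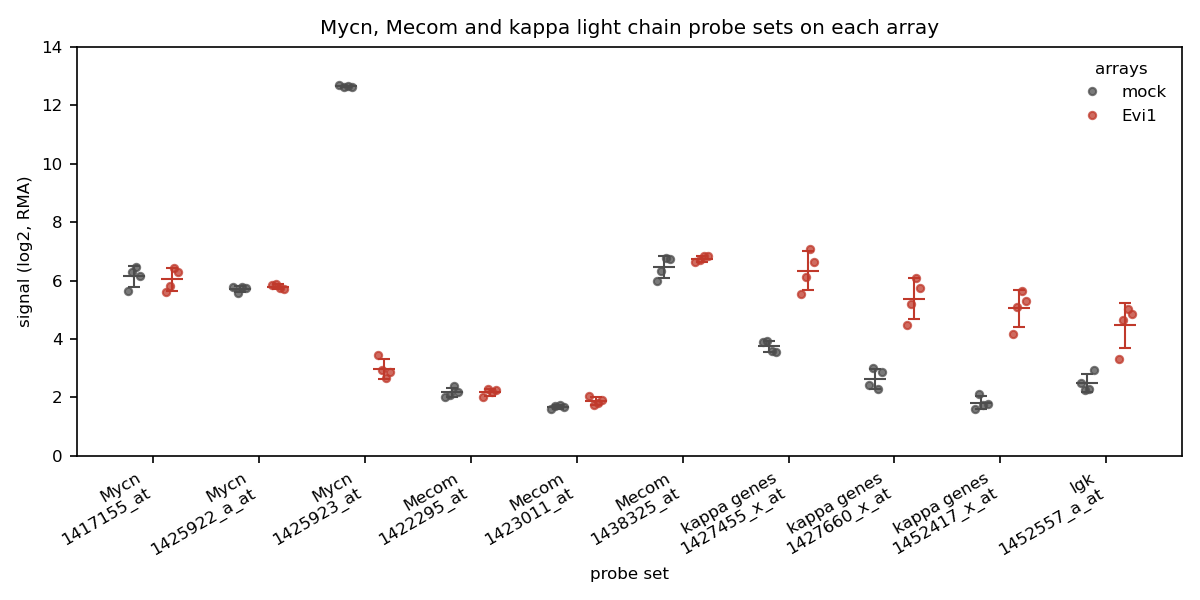
Signal (log2) of the Mycn, Mecom and kappa light chain probe sets on each of the 8 arrays, with points for arrays, horizontal bars for group means and error bars for SD (n = 4). The Mycn probe set 1425923_at lay at 12.65 in mock and 2.98 in Evi1 cells, the other Mycn and the Mecom probe sets differed by 0.29 or less, and the 4 kappa probe sets shown were higher in every Evi1 array. Of the Igk probe sets only the one with the greatest difference is shown. The others differed by -0.15 to 0.20, with groups that overlapped.

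Across the genome, 3 of 45037 probe sets passed the threshold, 2 that rose and 1 that fell. Of 18193 genes, each taken at its representative probe set, 1 was called lower (Mycn) and 0 were called higher. The Mycn call rests on that probe set alone, which the other Mycn probe sets did not follow. Without adjustment, 4588 probe sets (10.2%) had a limma p under 0.05, 2296 higher and 2292 lower. The groups did not overlap in 6.45% of probe sets, against 2.86% given by chance. The ordinary 2-sample test called 1 probe set. Among genes on the higher side, the 5 with the smallest p were the phosphatase regulator gene Ppp1r16b (0.55 ± 0.09, SE), the chaperone partner gene Hspbp1 (0.59 ± 0.09), the glycine transporter gene Slc6a9 (0.51 ± 0.08), Igk, and the microtubule-binding protein gene Eml2 (0.57 ± 0.10). Each was higher in every Evi1 array than in any mock array, at adjusted p = 0.353. These are values of the representative probe sets: the other probe set of Slc6a9 differed by 0.06 and that of Ppp1r16b by 0.31. Apart from Mycn, no gene named from here on passed. Their adjusted p lay between 0.353 and 0.996, and their differences are given as measured values. The hybridization spike-ins were brighter on the Evi1 arrays by 0.25 (11.38 ± 0.12 against 11.13 ± 0.07, SD, n = 4; exact permutation p = 0.0286, 0.114 adjusted over 4 controls). Whether equal amounts were added to each array is not known here. Centring the arrays on the spike-in median moved every probe set by -0.31. With that scaling 13 probe sets rose and 15217 fell, and the means of all 20 gene lists were lower in Evi1 cells. Differences below are therefore relative to the bulk of probe sets.

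The introduced gene was not visible at its own locus. The brightest Mecom probe set, 1438325_at, stood at 6.45 ± 0.37 in mock and 6.75 ± 0.10 in Evi1 cells (SD, n = 4), a difference of 0.29 (95% interval -0.07 to 0.66; limma, adjusted p = 0.567). Probe set 1423011_at differed by 0.20 (0.01 to 0.40; adjusted p = 0.476) at a level of 1.68 in mock cells, and 1422295_at by 0.01 (-0.22 to 0.23; adjusted p = 0.984). Probe sets outside the transduced sequence do not measure it, and the position of these was not analysed here, so they do not check the labels. Among genes tied to Evi1 in blood stem cells, Gata2, a transcription factor of stem cells, differed by 0.19 (-0.24 to 0.63), the adhesion receptor gene Adgrg1 by 0.24 (-0.12 to 0.61) and the integrin gene Itga6 by 0.01 (-0.23 to 0.26). With each array left out in turn, 1438325_at differed by 0.14 to 0.40, Gata2 by -0.0009 to 0.34 and Adgrg1 by 0.09 to 0.35, each lowest without mock replicate 1.

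Lymphoid genes leaned to the higher side in Evi1 cells. Both lists passed camera at the preset correlation, not with an estimated one (adjusted p = 0.114 for each), and no single member passed. The 17 measured B lineage genes had a mean difference of 0.24 ± 0.07 (SE between arrays), with 13 members higher and 4 lower. In limma 0 passed, 3 were higher and 0 lower at an unadjusted p under 0.05, and 0 passed when adjusted over the list alone. The interleukin 7 receptor gene Il7r was at 5.88 ± 0.59 in mock and 6.64 ± 0.18 in Evi1 cells (SD, n = 4). With each array left out in turn Il7r differed by 0.47 to 0.90, and its other probe set differed by 0.22. The recombinase gene Rag1, the B cell receptor component Cd79a and the adaptor Blnk differed by 0.59 ± 0.21, 0.30 ± 0.12 and 0.30 ± 0.14 (SE). The 18 measured T and NK cell genes had a mean difference of 0.21 ± 0.04, with 15 higher and 3 lower. In limma 0 passed, 5 were higher and 0 lower unadjusted, and 2 passed when adjusted over the list alone. Those were the granule protein gene Nkg7 (0.38 ± 0.11) and the NK receptor gene Klrd1 (0.46 ± 0.13). The T cell receptor component Cd3g and the chemokine gene Ccl5 differed by 0.37 ± 0.13 and 0.70 ± 0.24. In camera at the preset correlation the adjusted p was 0.00801 for the B lineage and 0.00238 for the T and NK list, against 0.114 for each with an estimated correlation. The estimates were 0.0005 and 0.018, against the preset 0.01. For the B lineage list the estimate lay under the preset value, so correlation between its genes does not account for the lost call. What does was not tested. The 4 Evi1 arrays lay above the 4 mock arrays in both (exact permutation p = 0.0286, the smallest possible, and 0.143 adjusted over the lists, the lowest this test gives with 4 lists at that p). In each list 6 members lay above the median signal of all probe sets, and both means were lower, at -0.07 and -0.11, after centring on the spike-ins. Without the lower part of the genes by signal, which left 6 members in each list, the means were 0.30 and 0.26 and the calls were lost, at adjusted p = 0.542 and 0.129. The B lineage call was lost without mock replicate 2 (0.0542) or Evi1 replicate 3 (0.0857), at means of 0.23 and 0.21.

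**Figure D2:**
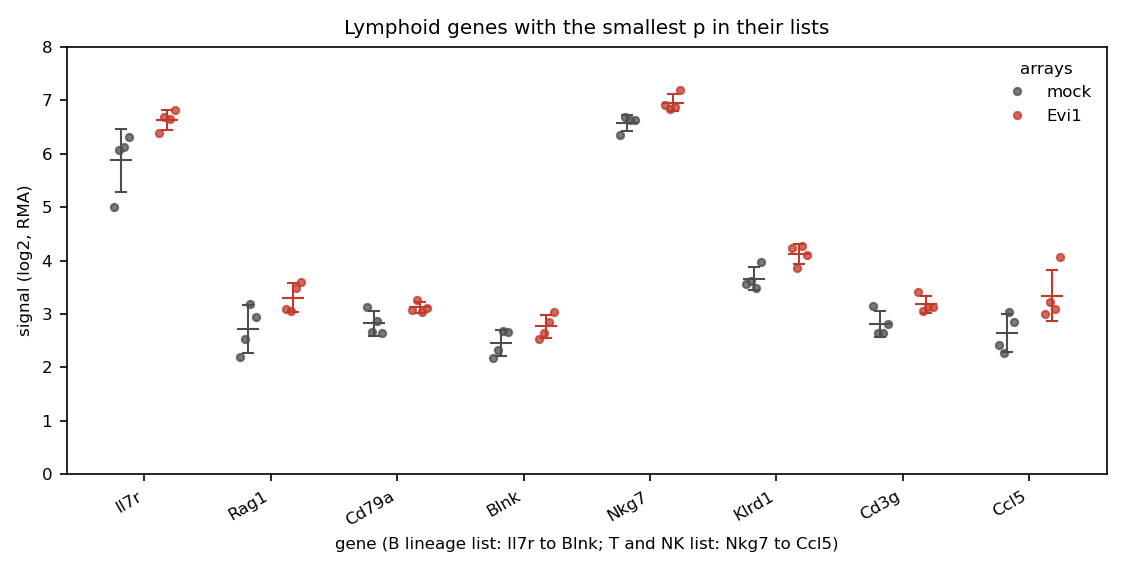
Signal (log2) of the B lineage and T and NK list members with the smallest p on each of the 8 arrays, with points for arrays, bars for group means and error bars for SD (n = 4). Il7r lay at 5.88 in mock and 6.64 in Evi1 cells and Nkg7 at 6.57 and 6.96. None of the 8 genes passed singly, and differences under 0.31 turn to lower when arrays are centred on the spike-ins.

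Markers of the myeloid lineages differed in both directions. Of 25 neutrophil and granule genes 0 passed in limma, with 4 higher and 1 lower unadjusted and 0 when adjusted over the list alone. The gelatinase gene Mmp9 was higher by 0.76 ± 0.22 (SE) and the iron-binding granule protein gene Lcn2 by 0.47 ± 0.15, whereas the collagenase gene Mmp8 was lower, at -0.44 ± 0.15. The list mean was 0.13 ± 0.08 (camera, adjusted p = 0.179), and 0.08 to 0.16 with each array left out in turn. Of 30 monocyte, macrophage and dendritic cell genes 0 passed, with 5 higher and 4 lower unadjusted, and 1 passed when adjusted over the list alone. That was Ms4a7, a membrane protein gene of macrophages, at 5.78 ± 0.02 in mock and 5.33 ± 0.15 in Evi1 cells (SD, n = 4). The galectin gene Lgals3 (-0.34 ± 0.09) and the macrophage pore protein gene Mpeg1 (-0.21 ± 0.08) were on the same side and the transcription factor gene Irf8 (0.25 ± 0.09) on the other. The remaining members that were higher unadjusted were all MHC class II genes, which present antigen. These were H2-Aa (0.38 ± 0.14), H2-Ab1 (0.44 ± 0.18), H2-Eb1 (0.54 ± 0.21) and Cd74 (0.58 ± 0.24). The list mean was 0.01 and the median -0.02, opposite in sign (camera, lower, adjusted p = 0.748).

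Among erythroid, megakaryocytic, mast cell and stromal markers no list passed the test with all 8 arrays. In limma 0 of 28 erythroid genes passed, with 0 higher and 1 lower unadjusted (mean 0.01 ± 0.04, median -0.01; camera, lower, adjusted p = 0.912). The erythroid transcription factor gene Klf1 differed by -0.18 ± 0.09 and the globin gene Hba-a2, whose near-identical copies can cross-hybridize, by 0.31 ± 0.17. Of 28 megakaryocyte and platelet genes 0 passed, with 2 higher and 0 lower unadjusted (mean 0.05 ± 0.10; adjusted p = 0.325). The list was called without Evi1 replicate 1 (mean 0.12; camera, adjusted p = 0.0376, and adjusted p = 0.738 with an estimated correlation), and without mock replicate 1 the mean was -0.01 (adjusted p = 0.996). Among these was the purinergic receptor gene P2rx1 at 0.34 ± 0.12. The von Willebrand factor gene Vwf was at -0.43 ± 0.24. Of 21 mast cell, basophil and eosinophil genes 0 passed, with 1 higher and 3 lower unadjusted (mean 0.01 ± 0.06, median -0.02; camera, lower, adjusted p = 0.815). The eosinophil granule gene Prg2 was at 0.42 ± 0.14 and the interleukin 5 receptor gene Il5ra at -0.25 ± 0.08. Of 22 stromal and endothelial genes 0 passed, with 1 higher and 0 lower unadjusted (mean -0.01 ± 0.03; adjusted p = 0.815). Sparc, a matrix protein gene, differed by 0.25 ± 0.11. In these 4 lists 0 members passed when adjusted over the list alone.

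Stem and progenitor cell genes showed no change outside Mycn that passed the test. Of 30 measured, 1 was called lower and 0 rose, also when adjusted over the list alone. The call rests on the Mycn probe set described above, which the other Mycn probe sets did not follow. At an unadjusted p under 0.05 no other member was added. The list's mean was -0.28 and its median 0.04 (camera, lower, adjusted p = 0.912). Without Mycn, a version chosen after the data were seen, the mean of the remaining 29 was 0.04 (camera, adjusted p = 0.685). The signalling receptor gene Slamf1 differed by -0.22 ± 0.11 (SE) and the angiopoietin gene Angpt1 by 0.15 ± 0.10. With each array left out in turn Slamf1 differed by -0.28 to -0.11 and Angpt1 by 0.07 to 0.21. Other probe sets of Slamf1 differed by -0.09 to 0.36, and the other one of Angpt1 by -0.13. Of 22 HOX genes 0 passed in limma or when adjusted over the list alone and 0 had an unadjusted p under 0.05, with Hoxa10 at 0.39 ± 0.22 and a list mean of -0.02 ± 0.03 (adjusted p = 0.815). With each array left out in turn Hoxa10 differed by 0.18 to 0.54, and its other probe set differed by -0.14.

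Among pathways that have been tied to EVI1 no list passed the test. Of 17 genes described as EVI1 targets 0 passed, also when adjusted over the list alone, with 0 higher and 1 lower unadjusted. That was Fos, an AP-1 transcription factor gene, at 9.32 ± 0.30 in mock and 8.78 ± 0.26 in Evi1 cells (SD, n = 4). Their mean was -0.01 ± 0.05 (SE; camera adjusted p = 0.815; median 0.01, which differs in sign). The kinase gene Map3k14 differed by 0.33 ± 0.15, and its other probe set by 0.01. Of 38 PI3K-AKT-mTOR genes 0 passed in limma, with 5 higher and 2 lower unadjusted and 0 when adjusted over the list alone (mean 0.02 ± 0.03, median -0.01; adjusted p = 0.815). The phosphatase gene Inpp4b was lower, at -0.49 ± 0.13, and the kinase gene Akt1, the stress-induced mTOR inhibitor gene Ddit4 and the AKT phosphatase gene Phlpp2 were higher, at 0.36 ± 0.12, 0.35 ± 0.11 and 0.24 ± 0.08. The other probe set of Inpp4b differed by 0.03, that of Phlpp2 by 0.10 and those of Akt1 by -0.14 to 0.35. Of 29 Polycomb genes 0 passed, with 2 higher and 2 lower unadjusted (mean 0.03 ± 0.03; adjusted p = 0.815). When adjusted over the list alone 1 passed, Ring1, a subunit of Polycomb repressive complexes, at 7.03 ± 0.13 in mock and 7.48 ± 0.13 in Evi1 cells (SD, n = 4). Of 35 TGF-beta and SMAD genes 0 passed, with 3 higher and 2 lower unadjusted and 0 when adjusted over the list alone (mean 0.04 ± 0.04; adjusted p = 0.748). The ubiquitin ligase gene Smurf1 differed by 0.35 ± 0.08 and the receptor gene Tgfbr1 by -0.28 ± 0.09. The other probe set of Smurf1 differed by 0.06 and those of Tgfbr1 by -0.34 to 0.10.

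Cell cycle genes did not pass as a list. Of 43 cell cycle genes 0 passed in limma, with 8 higher and 0 lower unadjusted and 0 when adjusted over the list alone. The spindle gene Prc1 differed by 0.32 ± 0.08 (SE), the replication gene Cdc45 by 0.27 ± 0.08, the thymidine kinase gene Tk1 by 0.52 ± 0.15 and the ubiquitin-conjugating enzyme gene Ube2c by 0.30 ± 0.08. The mean, 0.07 ± 0.01, was higher in all 4 Evi1 arrays than in any mock array (exact permutation p = 0.0286, 0.143 adjusted). Camera missed the threshold (adjusted p = 0.0523; adjusted p = 0.129 with an estimated correlation). The list was called with genes averaged over their probe sets (adjusted p = 0.000288) and without Evi1 replicate 4 (adjusted p = 0.0356, and adjusted p = 0.153 with an estimated correlation). Its median, 0.03, lay at percentile 82.45 of 10000 random lists matched on signal and gene length. Of 31 p53, CDK inhibitor and apoptosis genes 0 passed, with 1 higher and 7 lower unadjusted (mean -0.04 ± 0.02; adjusted p = 0.179). When adjusted over the list alone 1 passed, the CDK inhibitor gene Cdkn2d at 0.52 ± 0.12. The p53-responsive genes Zmat3, Trp53inp1 and Fas stood at -0.32 ± 0.09, -0.29 ± 0.09 and -0.33 ± 0.11. Of 30 ribosome biogenesis and MYC-responsive genes 0 passed, with 6 higher and 0 lower unadjusted and 0 when adjusted over the list alone (mean 0.05 ± 0.03; adjusted p = 0.19). Examples are the spermidine synthase gene Srm (0.26 ± 0.09) and the nucleolar gene Nop2 (0.24 ± 0.10).

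Interferon and immediate early genes did not pass as lists. Of 29 interferon response genes 0 passed in limma, with 1 higher and 3 lower unadjusted. When adjusted over the list alone 3 passed, the antiviral genes Ifit3 (-0.52 ± 0.11, SE) and Rsad2 (-0.52 ± 0.11) and, in the other direction, the tetherin gene Bst2 (0.45 ± 0.09). The list mean was -0.09 ± 0.05 (camera, adjusted p = 0.115), and 19 members were lower and 10 higher. The list was called without Evi1 replicate 4 (adjusted p = 0.00419, and adjusted p = 0.153 with an estimated correlation), the array with the highest list mean of all 8 (0.0988 relative to their mean). Of 24 immediate early and heat shock genes, which also respond to cell handling, 0 passed, with 1 higher and 6 lower unadjusted and 0 when adjusted over the list alone. Egr1, Jun and Dusp1 were at -0.33 ± 0.09, -0.45 ± 0.15 and -0.54 ± 0.17. The list mean was -0.08 ± 0.07 (camera, adjusted p = 0.19), and -0.13 to -0.05 with each array left out in turn, with 13 members lower and 11 higher with all arrays. This list was called without Evi1 replicate 4 (adjusted p = 0.0314, and adjusted p = 0.549 with an estimated correlation), the array with the next to highest list mean (0.11). Of 4 sex-linked genes measured 0 passed in limma or when adjusted over the list alone, and 0 had an unadjusted p under 0.05. Xist was at 9.86 ± 0.11 in mock and 9.84 ± 0.39 in Evi1 cells (SD, n = 4), and the Y-linked gene Kdm5d was at 2.27 ± 0.15 and 2.10 ± 0.26 (adjusted p of the list 0.878).

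**Figure D3:**
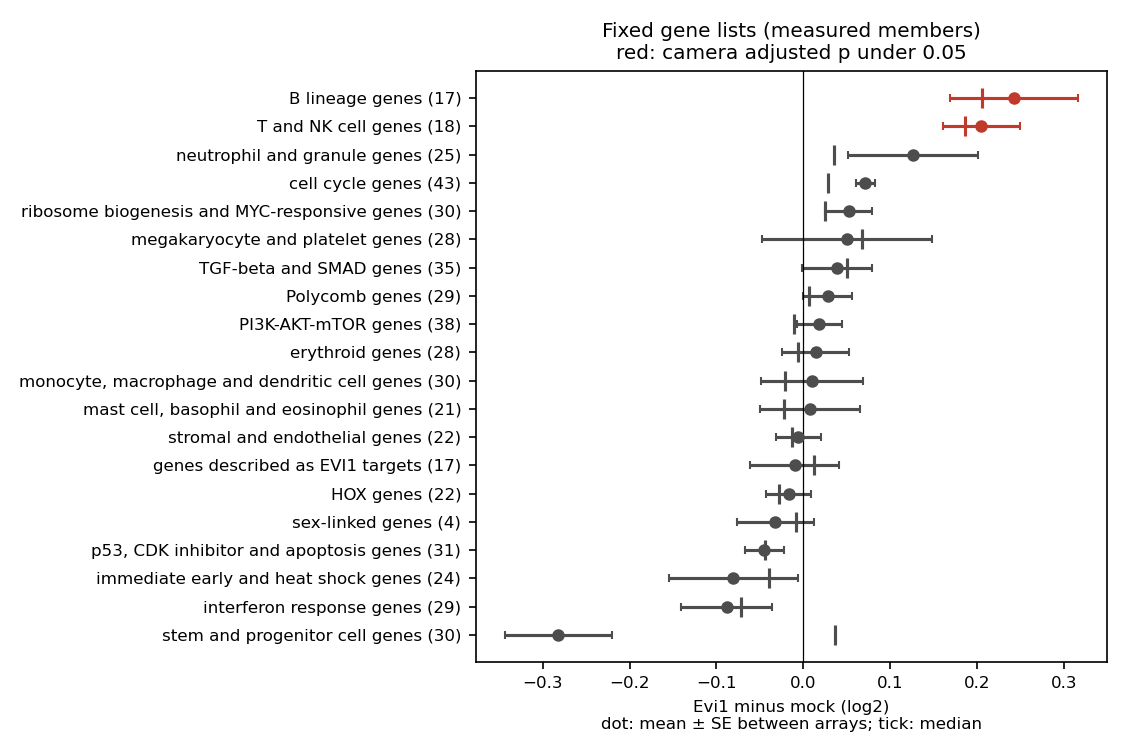
Difference between Evi1 and mock cells (log2, relative to the bulk of probe sets) for the 20 gene lists, with dots for the mean over members, error bars for the SE between arrays and ticks for the median over members. The B lineage and T and NK lists, at 0.24 and 0.21, passed camera at the preset correlation and not with an estimated correlation (adjusted p = 0.114 for each). All 20 means were below 0 when arrays were centred on the spike-ins, and the mean of the stem and progenitor list rests on Mycn.

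RNA quality controls showed no difference that passed the test. The signal of the 3' end of Gapdh minus that of the 5' end was 5.33 ± 0.03 in mock and 5.31 ± 0.20 in Evi1 cells (SD, n = 4; exact permutation p = 0.771), and for beta-actin it was 0.88 ± 0.08 and 0.86 ± 0.12 (exact permutation p = 0.857). The Gapdh 3' end minus its middle part was 3.32 ± 0.26 and 2.98 ± 0.37 (exact permutation p = 0.171).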

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

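In each group of 4 arrays, single arrays far from the other 3 were sought by Dixon's ratio (critical value 0.829) for every named gene, named probe set, control and list mean. Of 232 groups tested, 14 stood out, against 11.6 that chance gives at about 1 in 20. Mock replicate 4 was far from the other mock arrays for Ppp1r16b (3.31, others 3.58 to 3.63), Slamf1 (4.57, others 4.08 to 4.15) and Klf1 (3.35, others 3.57 to 3.61). Mock replicate 1 was far for Cdkn2d (4.12, others 4.44 to 4.48) and for the mean of the genes described as EVI1 targets (-0.0877 relative to the mean of all arrays, others 0.03 to 0.04). Mock replicate 2 was far for Pcgf3 (6.41, others 6.54 to 6.56) and mock replicate 3 for Bop1 (7.77, others 7.73 to 7.74).

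Among the Evi1 arrays, replicate 1 was far from the others for Hba-a2 (8.04, others 8.62 to 8.72), Vwf (3.22, others 4.12 to 4.23), Itga6 (8.44, others 8.74 to 8.76) and the mean of the stem and progenitor genes (-0.25, others -0.12 to -0.09). Replicate 2 was far for Pdgfrb (4.93, others 4.84 to 4.85) and Ppan (7.10, others 7.28 to 7.31), and replicate 4 for the mean of the Polycomb genes (0.0498, others up to 0.01). The called kappa probe sets, Mycn 1425923_at and the Mecom probe sets had no such array.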

How the results depend on the processing

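Leaving out mock replicate 1 with Evi1 replicate 4, counting at an unadjusted p, the stem list without Mycn and the estimated correlation with an array left out were chosen after the data were seen. The 3 probe sets became 15230 with centring on spike-ins, which moves every probe set the same way. They became 6 with a variance trend and robust moderation, 1 with the ordinary 2-sample test, 4588 at an unadjusted p under 0.05, and 1 to 5 with arrays left out. The 1 gene became 5798 with centring on spike-ins, 2 with trend and robust moderation, and 1 to 2 with arrays left out. The 2 lists became 0 with an estimated correlation, 0 by exact permutation, 0 without the lower part of genes by signal, and 1 to 5 with arrays left out. In that order of list tests, adjusted p was 0.114, 0.143 and 0.542 for the B lineage list and 0.114, 0.143 and 0.129 for the T and NK list. The exact permutation says nothing about stability here, since with 4 lists at its smallest p, 0.0286, it gives no adjusted p under 0.143. With an estimated correlation, none of the lists called with an array left out was called. Without the lower part of genes the mean differences were 0.30 and 0.26, against 0.24 and 0.21, over fewer members. With arrays left out adjusted p spanned 0.00172 to 0.0857 for B lineage, 0.000256 to 0.0141 for T and NK and 0.0356 to 0.104 for cell cycle genes. It spanned 0.0376 to 0.996 for megakaryocyte, 0.00419 to 0.332 for interferon and 0.0314 to 0.826 for immediate early genes. Without both end arrays the interferon list reached 0.00601 and 1 probe set was called. The cell cycle list reached 0.000288 with genes averaged over probe sets. Unless fewer genes or arrays account for it, the cause was not tested.

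With the replicate block 2 probe sets, 1 gene and 2 lists were called, and the call on 1427455_x_at was lost (adjusted p = 0.403). Same-numbered arrays did not deviate together as a set (correlations of 0.17, -0.07, -0.02 and -0.13, against -0.31 to 0.29 for differently numbered pairs). The numbers thus showed no pairing, but so few correlations cannot exclude it. Of 1625 values of single genes under alternatives other than spike-in centring, 1624 kept their side of the threshold; Igk passed without Evi1 replicate 1 (adjusted p = 0.00538). All 47 such Mecom values, and the 3 with spike-in centring, stayed short of it. With spike-in centring, 35 of 87 values of single genes crossed it. The alternatives planned for 1 further gene were not run. No detection calls were used, so how far low signals lie above background is not known here.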

Other observations

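The MHC class II list with its test, the tests on Mycn, on the kappa probe sets and on the share of the main cell type, the lymphoid means with arrays left out, the splits for probe sets and the gene length trend were chosen after the results they concern were seen. MHC class II genes, which present antigen on B cells, dendritic cells and macrophages, were picked as a list because members were seen to be high in Evi1 cells, so the values below describe them and no test on the list decides whether they differ. Over 9 members the mean log2 difference was 0.42, and no member passed singly in limma. Of these, Cd74, H2-Aa, H2-Ab1, H2-Eb1 and Ciita also belong to the monocyte, macrophage and dendritic cell list, so the lists are not separate observations. The invariant chain gene Cd74 was at 6.64 ± 0.16 in mock and 7.22 ± 0.58 in Evi1 cells (SD, n = 4), H2-Eb1 at 6.35 ± 0.23 and 6.89 ± 0.45, and H2-Aa at 7.22 ± 0.23 and 7.59 ± 0.24. H2-DMb2, which has a near-identical neighbour in the genome, differed by 1.04 ± 0.18 (SE; limma, adjusted p = 0.353) and, in another probe set, by 1.13 ± 0.18, while a further one differed by -0.08 ± 0.09. H2-Oa, which modulates class II loading in B cells, was at -0.09 ± 0.08. The median of the list, 0.44, lay above all of 10000 random lists matched on signal and gene length (percentile 100). For the same reason this decides nothing about a trend with signal or length.

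With a variance trend and robust moderation together, 3 further probe sets were called. These were the kappa probe set 1427660_x_at (adjusted p = 0.00222, against 0.0532 otherwise) and probe sets of Cybb and Top2b. Cybb, the catalytic subunit of the phagocyte NADPH oxidase, differed by -0.34 ± 0.07 (SE; adjusted p = 0.0331 under those settings and 0.36 otherwise), and a probe set of Top2b, a topoisomerase gene, by -0.44 ± 0.07 (0.0331 and 0.353). Both were named after their values were seen. Shorter genes tended to be higher in Evi1 cells: across 10790 genes in the upper part by signal, which are not independent, the rank correlation of limma's statistic with genomic length was -0.188. Of the 35 splits of the arrays, 1, the real one, gave as strong a value, and the highest size among the others was 0.163.

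The Mycn probe set that fell by 9.68 on the log2 scale stood apart from all others, since the next greatest difference was 3.24. A lower level of the whole Mycn transcript is argued against by the other two probe sets, whose mean differed by -0.0161 (95% interval -0.31 to 0.28), and a difference in labelled target by the spike-ins, which left it at -9.99. A sequence carried by the mock construct alone stays open. The mock signal, at percentile 99.96 of all probe sets, may come from such a sequence. However, vector and probe sequences were not used here, and 0 other probe sets differed by over 5. The mock SD of 0.02 does not bear on this, since the median mock SD of 98 probe sets of similar level was 0.026. A loss of 1 form of the transcript after Evi1 transduction also stays open and untested.

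For the 2 kappa probe sets that rose, a single array as the source of the difference is argued against, since with each array left out in turn both differed by at least 2.35, although their calls were lost without some arrays. Mature B or plasma cells that passed the GFP sort, which would remove cells without the virus, cannot be told apart from transcription of the locus in the transduced cells, an untested effect of Evi1 included. The median of 10 of their genes, fixed after the kappa values were seen, was higher by 0.15, far below the kappa difference (exact permutation p = 0.0286, the smallest possible; for the list, camera p = 0.0119 and p = 0.0393 with an estimated correlation). Jchain, abundant in plasma cells, was at 2.31 ± 0.09 in mock and 2.35 ± 0.15 in Evi1 cells (SD, n = 4), and the B cell genes Ms4a1 and Cd22 differed by 0.11 ± 0.11 and 0.22 ± 0.14 (SE), while Mzb1 and Cd37 differed by 0.29 ± 0.10 and 0.41 ± 0.14. The brightest Ighm probe set, 1427351_s_at, had a high baseline, at 8.02 ± 0.07 and 8.19 ± 0.23. The other Ighm probe sets stood lower and differed by -0.25 to 0.29. What keeps it open is that the ratio of kappa to these transcripts in such cells was not measured.

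For the higher B lineage and T and NK lists, which share 0 genes, a trend with signal and gene length is argued against by matched random lists, all 10000 of which lay below the median of 0.21 over both lists (percentile 100). A lower share of the main cell type would raise erythroid, mast cell and stromal markers alike only if these come from other cells. Their list means were 0.01 ± 0.04, 0.01 ± 0.06 and -0.01 ± 0.03. The main cell type of the sorted fraction was not identified here, so these means do not decide the question. The lymphoid mean minus the mean of those lists differed by 0.22 (exact permutation p = 0.0286, the smallest possible). That contrast was picked after these means were seen, so its p decides nothing. It left out the neutrophil and megakaryocyte lists, with means of 0.13 and 0.05. A single array as the source of the difference is argued against by the means, at least 0.19 with each array left out, although the B lineage call was lost without Evi1 replicate 3 (adjusted p = 0.0857, mean 0.21 ± 0.07, SE) and mock replicate 2 (0.0542, 0.23 ± 0.09), against 0.24 ± 0.07 with all arrays. The T and NK call, at 0.0141 or less with any array left out, was lost with an estimated correlation (adjusted p = 0.114) and without the lower part of genes by signal (0.129). Chance is not excluded for these lists, since 15 of 35 splits of the arrays gave as many called lists. If the difference is real, more lymphoid cells in the sorted fraction and low-level transcription of lymphoid genes after Evi1 transduction remain as untested hypotheses. A lower share of the main cell type remains as well.

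Other splits of the 8 arrays into groups of 4 bear on the counts. For the counts of 3 probe sets and 1 gene called, the labelled split stood alone, at the smallest share that 35 splits can give. Of 35 splits 1, the real one, gave as many probe sets and 1 as many genes, and the highest of the others was 0 for each. The other splits put arrays of both levels of Mycn and kappa signal on each side, so these probe sets could hardly be called there. The share therefore says only that the called probe sets part the arrays as the labels do. It does not decide on chance or say that each call holds, and the call on 1427455_x_at was lost when any 1 of 6 arrays was left out. At an unadjusted p under 0.05, 1 of 35 splits gave as many as the 4588 probe sets, the next being 4363 for the split that exchanges mock replicate 2 with Evi1 replicate 1. For the 2 gene lists chance cannot be excluded, since 15 of 35 splits gave 2 or more, and the highest of the others was 5.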
